A study of Rattus norvegicus with 12 samples.

How the data were processed

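RNA was taken from hippocampal slice cultures of postnatal day 7 Wistar rats after 26 days in vitro, 4 slices per insert and 24 cultures per sample, in 4 groups of 3 samples: NT, control IgG, 11C7 and 7B12. Antibodies were given at 3 µg/ml from day 21 for 5 days, with medium changed every 2 days. Groups and replicate numbers were taken from the sample titles, and per the labels the replicates are separate cultures from different animals. RNA integrity was above 9 in each sample per the labels.

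Biotin-labelled cRNA was hybridised to Affymetrix rat arrays, per the labels' protocols. The authors used GCOS 1.4 and MAS5 per the submitters' processing notes, where the version of MAS5 is not given. The design text also names a further program for a filter on detection calls, a normalization per array and per gene, an analysis of variance and a 1.2-fold limit. The deposited values are ratios: the authors divided each probe set's values by a reference of that probe set, which the design text states as the control median. The values differ from that statement. Within a tolerance of 0.0015, 76.4% of probe sets had a median of 1 over the 12 arrays and 11.2% over the 6 control arrays, so the values look relative to the median of all 12 arrays. The remaining 7319 probe sets (23.6%) had a 12-array median under 1; they are called dim here as a name only, since the level behind a ratio is unknown. A constant divisor per probe set leaves differences between groups on the log2 scale as they are.

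The table holds 31099 probe sets, of which 57 spike-in controls were left out and 31042 tested. By the platform annotation given, 20826 probe sets (67.1%) have 1 gene symbol, 436 several and 9780 none here, and 14217 genes have a probe set with 1 symbol. Symbols were matched through Entrez identifiers for 20758 of them, which changed 0. Depth has no counterpart on these arrays, and with 3 arrays per group the number of arrays limits the precision. Each value was taken as log2 of the ratio less the median of its array. Since ratios carry no level, the planned filter on dim probe sets was not used.

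Tests, lists of genes, the rule for named genes and most of the alternatives were fixed before the data were examined; departures are given where they occur. Groups were fitted in limma 3.58.1 (R 4.3.3) with lmFit, 1 mean per group over all 12 arrays, contrasts and eBayes, with two-sided tests, Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05 on the adjusted p. The contrasts were both antibodies, 11C7 and 7B12 each against the mean of NT and IgG, IgG against NT, 7B12 against 11C7, and an F test over the 4 groups. The plan was eBayes with a mean-variance trend for intensities. The values turned out to be ratios, whose mean says nothing about brightness, and on simulated data the fit with the trend recovered 0 of the changed probe sets, so the fit without the trend was taken. That change was made after the data were seen, when it was known that no probe set passed in any of the 5 contrasts with either fit. Without the trend the test on simulated data over 31042 probe sets recovered, for 7B12, 90% of 50 changes of 8-fold, 68% of 4-fold, 38% of 2-fold and 2% of 1.5-fold. For 11C7 these were 88%, 72%, 28% and 2%, and for both antibodies 92%, 76%, 48% and 10%. The changes were placed only in probe sets with a 12-array median of 1, in independent noise without differences among replicate numbers. The median SD of the changed probe sets was 0.30 to 0.43, against 0.49 over all probe sets. These shares therefore do not hold for all probe sets of the real arrays. Among 30842 unchanged probe sets 7, 4 and 8 were called for both antibodies, 11C7 and 7B12.

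For the 32 lists (19 pathways and 13 sets of cell type markers) the probe sets of a gene with 1 symbol were averaged on the log2 scale, because the planned choice of the brightest probe set cannot be made from ratios. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists of a contrast. A second run estimated the correlation within each list, and in it no list passed in any contrast. On simulated data of independent genes without differences among replicate numbers, the list that had been shifted passed, and 0 of 31 other lists did. Because the genes were drawn independently, this does not show how often camera calls unchanged lists on the real arrays. Some genes belong to several lists, such as Fcer1g to the Fc receptor and microglia lists. Rtn4 was also tested by exact permutation of 6 against 6 arrays.

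By the rule for named genes, the 10 largest rises and 10 largest falls per contrast among passing probe sets with 1 symbol were to be named. As fewer passed, the 10 per direction with the smallest unadjusted p and at least 1.2-fold were taken and are said not to pass, beside Rtn4, its receptor genes and 2 to 4 members with the smallest p of each list described. The text prints part of these.

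Replicate numbers 1 to 3 occur in every group, so their pairing was checked before the fits were compared. Over the 23723 probe sets with a median of 1, the deviations from the group means of arrays with the same number correlated in 18 of 18 pairs by over 0.1 (0.194 to 0.668), while other pairs reached at most 0.154. Over all 31042 probe sets 17 of 18 pairs did, the lowest at 0.0861. All 12 arrays correlated best with arrays of their own number, and the first principal component of the 23723 probe sets (40.6% of the variance) lay 94.3% between numbers. The numbers were taken to pair the samples, from the first set. The labels do not say what a number shares.

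Alternatives were no scaling between arrays, quantile normalization, the trend, array weights, the replicate number as a block, only the groups of a contrast, leaving out each array, IgG or NT alone as the control, fry in place of camera, split controls, and the methods' one-way analysis of variance on these values and on values over the control median. Added after the data were seen were only probe sets with a median of 1, a pseudocount of 0.1, robust eBayes, the block with some of these or without each array, a block by hybridisation controls, and the probe set with the smallest SD per gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.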

Results

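Expression was measured on 12 Affymetrix rat arrays, each hybridised with 1 RNA sample from organotypic hippocampal slice cultures, which are slices of living brain tissue kept on a membrane so that much of their cell arrangement is preserved. Hippocampi of Wistar rats at postnatal day 7 were sliced at 350 µm and cultured at 33 °C for 26 days. From day 21 in vitro, 3 groups of cultures received an antibody at 3 µg/ml for 5 days. These were a control IgG, the monoclonal antibody 11C7, which binds amino acids 623 to 640 of Nogo-A, and the monoclonal antibody 7B12, which binds amino acids 763 to 820. Nogo-A is a membrane protein of oligodendrocytes and neurons, encoded by Rtn4 and known for limiting neurite growth. The remaining group, called NT, was not treated. Each group had 3 replicates, and each replicate pooled the RNA of 24 cultures. The number of arrays limits the precision of every value below. The deposited values are ratios per probe set, so the level of a gene cannot be set against that of another gene. Changes are log2 differences between group means with their standard error (SE), and a list of genes is given by the median change of its measured members. Arrays with the same replicate number resembled each other across the groups. Many lists differed among the numbers by camera at its preset correlation, but none did with an estimated correlation. Among them were general neuron, myelin and microglial markers and the Fc receptor, interferon, inflammatory and ribosomal genes. Results that changed when the number was fitted as a block are therefore given with that value. Leaving out 1 array without the block makes the groups uneven in the numbers, so calls that ended in this way are also given with the block.

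The question for 7B12 was which genes differ when Nogo-A is bound by an antibody to its 763 to 820 stretch. Inflammatory genes rose, by a median of 1.53 (2.88-fold), with 35 of 37 measured members above 0 and all 3 arrays above all 6 control arrays. The mean of the list was 1.57 ± 0.51 (SD, n = 3 arrays) in 7B12, -0.02 ± 0.22 in NT and 0.02 ± 0.33 in IgG. Saa3, an acute-phase serum amyloid A gene, stood 6.91 ± 1.33 (SE) above the controls (120.4-fold). Il1b, the gene of the cytokine interleukin-1β, stood 3.18 ± 0.63 above them, the interferon-induced chemokine gene Cxcl10 2.79 ± 0.55, and Serping1, which encodes the C1 inhibitor of complement, 1.19 ± 0.25. Interferon and antigen presentation genes rose by a median of 0.96 (1.95-fold, 33 of 35 members above 0). Among them were Gbp2, a guanylate-binding protein gene (2.79 ± 0.45), the ubiquitin-like Isg15 (2.34 ± 0.46), the transcription factor gene Irf7 (2.44 ± 0.55) and Oasl (2.14 ± 0.49). Genes of Fc receptors, complement C1q and antibody handling rose by a median of 0.53 (16 of 19 members above 0), with Fcgr3a at 1.65 ± 0.41, Fcer1g at 1.13 ± 0.31, C3ar1 at 1.31 ± 0.38 and the kinase gene Lyn at 0.82 ± 0.24. Microglial and macrophage markers rose by a median of 0.39 (24 of 29 members above 0), with the lysozyme gene Lyz2 2.64-fold above the controls, Ms4a7 at 2.84 ± 0.64, the oxidase subunit gene Cybb at 1.76 ± 0.41 and the mannose receptor gene Mrc1 at 2.46 ± 0.61. Blood cell markers stood at a median of 0.78 beside them (adjusted p = 0.0895), with array means of 0.87, 0.99 and 0.47. Unlike inflammatory genes, the Fc receptor and microglial lists overlapped with the controls. Their lowest 7B12 means were 0.36 and 0.38, against 0.52 and 0.64 in the highest control array. Above the controls of the same number, 7B12 stood 0.62 ± 0.13 (SD, n = 3) for Fc receptor and 0.62 ± 0.16 for microglial genes.

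Ribosomal protein genes also rose with 7B12, by a median of 0.23 (23 of 27 members above 0), although Rpl3 was lower (-1.13). Markers of oligodendrocytes and myelin fell (median change -0.23, 24 of 28 members below 0), among them Car2, a carbonic anhydrase gene (-0.67 ± 0.22), and Ermn (-0.71 ± 0.38). The myelin mean in 7B12 1 (-0.57) was close to that in NT 1 (-0.56), and the lowest IgG array stood at -0.67. Markers of oligodendrocyte precursors fell (median change -0.25, 8 of 9 members below 0), with Ptprz1 at -0.44 ± 0.17 and the growth factor receptor gene Pdgfra at -0.44 ± 0.19. Axon guidance genes fell (median change -0.11, 32 of 47 members below 0), with the semaphorin receptor gene Nrp1 at -0.99 ± 0.35. General neuron markers stood at a median of -0.02 (adjusted p = 0.820) and astrocyte markers at -0.12 (adjusted p = 0.0614, and 0.0464 with the replicate number as a block, where adjusted p = 0.884 with an estimated correlation).

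Of 32 lists, 8 passed in 7B12 by camera at its preset correlation. The adjusted p was 1.93e-23 for inflammatory genes (adjusted p = 0.204 with an estimated correlation), 1.37e-20 for interferon genes (0.204), 3.11e-06 for the Fc receptor list (0.727) and 3.41e-06 for microglia (0.868). It was 0.000961 for ribosomal proteins (adjusted p = 0.977 with an estimated correlation), 0.00121 for myelin (0.977), 0.00915 for oligodendrocyte precursors (0.339) and 0.0408 for axon guidance (0.353). Adjusted over the list alone, 19 inflammatory, 16 interferon, 6 Fc receptor and 6 microglial genes passed, all of them higher. The inflammatory, interferon, Fc receptor and microglial calls were past the threshold without any single array. The ribosomal call ended without 7B12 3 (adjusted p = 0.786, median 0.063), and the myelin call without NT 3 (0.104, median -0.10), IgG 3 (0.0920, median -0.098) or 7B12 1 (0.259, median -0.11). The precursor call ended without NT 3 (0.0504) or 7B12 2 (0.0706), and the axon guidance call without NT 2 (0.134, median -0.070), IgG 2 (0.0934), 7B12 1 (0.0626) or 7B12 3 (0.538, median 0.020). Leaving out 1 array from the fit with the block ended only the precursor call, without 7B12 3 (adjusted p = 0.0765), and the axon guidance call, without NT 2 (0.0695) or 7B12 3 (0.361, median -0.051). The ribosomal call ended also against IgG alone (adjusted p = 0.0610), and the precursor call with the probe set of the smallest SD for each gene (0.0706). The axon guidance call ended with those probe sets (adjusted p = 0.0706), against IgG alone (0.0868), with array weights (0.0716) or with values as deposited (0.0506).

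Single genes with the smallest p in 7B12 included the integrin gene Itgal (3.86 ± 0.70 above the controls, 14.5-fold), the prostaglandin E synthase gene Ptges (3.35 ± 0.60), Slamf9 (3.04 ± 0.56), Fxyd2 (2.79 ± 0.50), Lgals9, which encodes galectin-9 (1.48 ± 0.26), and Adam22 (1.57 ± 0.25), though Adam22 also stood 2.79 ± 0.29 higher in IgG than in NT. Lower in 7B12 were Mmrn2, which encodes an endothelial matrix protein (-2.32 ± 0.37), Cd200r1l (-2.13 ± 0.37), Igf1, the gene of insulin-like growth factor 1 (-1.77 ± 0.34), the leukotriene C4 synthase gene Ltc4s (-2.18 ± 0.52) and Irx1 (-2.02 ± 0.46). In each of these the 3 arrays lay on one side of the control mean. None passed: limma called 0 of 31042 probe sets, the smallest adjusted p was 0.438, and 1615 had an unadjusted p under 0.05. A share of 0.05 of those tested is 1552, but this fit leaves the differences among the numbers in its spread. Other splits of these arrays within numbers gave at most 1011 with at least 1.2-fold. All 1615 had at least 1.2-fold, 958 higher and 657 lower (2871 with the replicate number as a block, 1585 higher and 1286 lower).

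When the number was a block and the 11C7 arrays were left out, a setting chosen after the data were seen, 68 probe sets passed in 7B12, 61 higher and 7 lower. They held 49 named genes. Saa3, Il1b, Tlr2 and Lcn2 came from the inflammatory list, Gbp2 and Psmb8 from the interferon list, Fcgr3a and Fcer1g from the Fc receptor list, and Lyz2, Mrc1, Ms4a7 and again Fcer1g from the microglia list. Itgal had the smallest adjusted p (0.00422). Named after their values were seen, Cxcl13, a chemokine gene for B cells, stood 4.05 ± 0.22 above the controls (adjusted p = 0.0187), the iron-binding lipocalin gene Lcn2 3.39 ± 0.29 (0.0384) and the receptor gene Tlr2 1.75 ± 0.09 (0.0187), each in 3 of 3 arrays. Igf1 was lower (-1.77, adjusted p = 0.0388). Whether these genes are particular to 7B12 is open, since the 11C7 arrays differed and a wrong label on 11C7 1 cannot be excluded. In the left-out array 11C7 1 the log2 values of Saa3 (6.62), Cxcl13 (3.34) and Tlr2 (1.00) stood as high as in 7B12 1 (6.52, 2.41 and 0.70). In 11C7 2 and 3 they were lower (0.02 and 0.61 for Saa3). Without a block, 10 probe sets passed in 7B12 when 11C7 1 was left out of the shared estimate of the spread.

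For 11C7, inflammatory genes rose by a median of 0.59, with 35 of 37 members above 0, and interferon genes by 0.40 (1.32-fold), with 30 of 35 above 0. The mean of the inflammatory list was 1.54 in 11C7 1, 0.30 in 11C7 2 and 0.22 in 11C7 3, against -0.35 to 0.28 in the 6 control arrays. Above the controls of the same number it stood 1.43, 0.61 and 0.018. Serping1 stood 0.80 ± 0.25 (SE) above the controls, the protease inhibitor gene Serpina3n 0.93 ± 0.34, Cxcl10 1.43 ± 0.55, Oas1a 1.23 ± 0.45 and Isg15 1.15 ± 0.46. Glutamate receptor and postsynaptic genes fell (median change -0.26, 38 of 43 members below 0), with the NMDA receptor gene Grin2d at -1.75 ± 0.69 and the scaffold genes Shank1 at -2.07 ± 0.83 and Shank2 at -1.31 ± 0.69. GABA receptor and synthesis genes fell (median change -0.32, 13 of 16 members below 0), with the GABA transaminase gene Abat at -2.63 ± 0.62 and Gabra2 at -0.57 ± 0.26. Interneuron markers fell (median change -0.26, 16 of 18 members below 0), with the calretinin gene Calb2 at -0.41 ± 0.23. General neuron markers were lower in 11C7 2 (0.37) than in the other arrays numbered 2, which were NT 2 (1.23), IgG 2 (0.91) and 7B12 2 (1.04).

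By camera, 5 lists passed in 11C7, with adjusted p = 2.33e-07 for inflammatory, 0.000111 for interferon, 0.000143 for glutamate receptor, 0.0191 for GABA and 0.0329 for interneuron genes; each had adjusted p = 0.838 with an estimated correlation. Adjusted over the list alone, Abat passed and no inflammatory or interferon gene did. Without 11C7 1 the inflammatory median was 0.17 (adjusted p = 0.155, and 0.0989 with the number as a block) and the interferon median 0.09 (0.418, and 0.484 with the block). The 3 calls of lower lists ended without 11C7 1 (adjusted p = 0.301, 0.301 and 0.468, with medians of -0.057, -0.042 and -0.068), NT 2 (0.219, 0.286 and 0.403, with medians of -0.060, 0.021 and -0.014) or IgG 2 (0.128, 0.156 and 0.402, with medians of -0.064, -0.10 and -0.0091), and those of GABA and interneuron genes without 11C7 3 (0.0759 and 0.174, with medians of -0.36 and -0.37). In fits with the number as a block the 3 passed without any of these arrays and ended without 11C7 2 (adjusted p = 0.605, 0.352 and 0.194, with medians of 0.0019, -0.056 and -0.073). The GABA call ended also against IgG alone (adjusted p = 0.119) and with the probe set of the smallest SD for each gene (0.104), and the interneuron call against IgG alone (0.0877). When the block placed 11C7 2 with the arrays numbered 1, which also makes the groups uneven in the numbers, the 3 medians turned to 0.17, 0.16 and 0.37 (adjusted p = 0.458, 0.902 and 0.458). With the number as a block 14 lists passed, and 0 with an estimated correlation as well. The additions (adjusted p = 0.595 or more with the block and an estimated correlation) were lower presynaptic genes (0.0246) and markers of neurons in general (0.00123), of hippocampal principal neurons (0.0246) and of astrocytes (0.0246), and higher myelin (0.00855), microglial (0.0255), Fc receptor (0.0376), unfolded protein (0.0255) and cell cycle genes (0.0246). Against the controls of the same number, presynaptic means were 0.15, -0.62 and 0.036 in 11C7 1, 2 and 3, those of general neuron markers 0.071, -0.70 and -0.081, and those of hippocampal principal neurons 0.20, -0.71 and 0.037. In 11C7 3 the astrocyte (0.15), myelin (-0.048), microglial (-0.11), Fc receptor (-0.093) and cell cycle means (-0.19) went the other way.

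Among single genes with the smallest p in 11C7, lower ones were Fap, which encodes a fibroblast protease (-1.83 ± 0.34), the cadherin gene Cdh8 (-2.07 ± 0.39), the adaptor gene Crkl (-1.18 ± 0.24) and Immp2l (-2.37 ± 0.44), with all 3 arrays below the control mean. All 10 named rises came from dim probe sets, whose 12-array median was under 1, such as Ttc34 (2.16 ± 0.35) and the aldo-keto reductase gene Akr1c14 (1.97 ± 0.38). So did 6 of the 10 named falls. In the other contrasts, dim probe sets gave 2 of 10 rises and 3 of 10 falls in 7B12, and 2 and 7 in both antibodies. They gave 8 and 6 in IgG against NT, and 6 and 6 in 7B12 less 11C7. None passed in 11C7: limma called 0 of 31042 probe sets (smallest adjusted p = 0.561), and 999 had an unadjusted p under 0.05. All 999 had at least 1.2-fold, 307 higher and 692 lower (1752 with the replicate number as a block, 652 higher and 1100 lower).

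**Figure D1:**
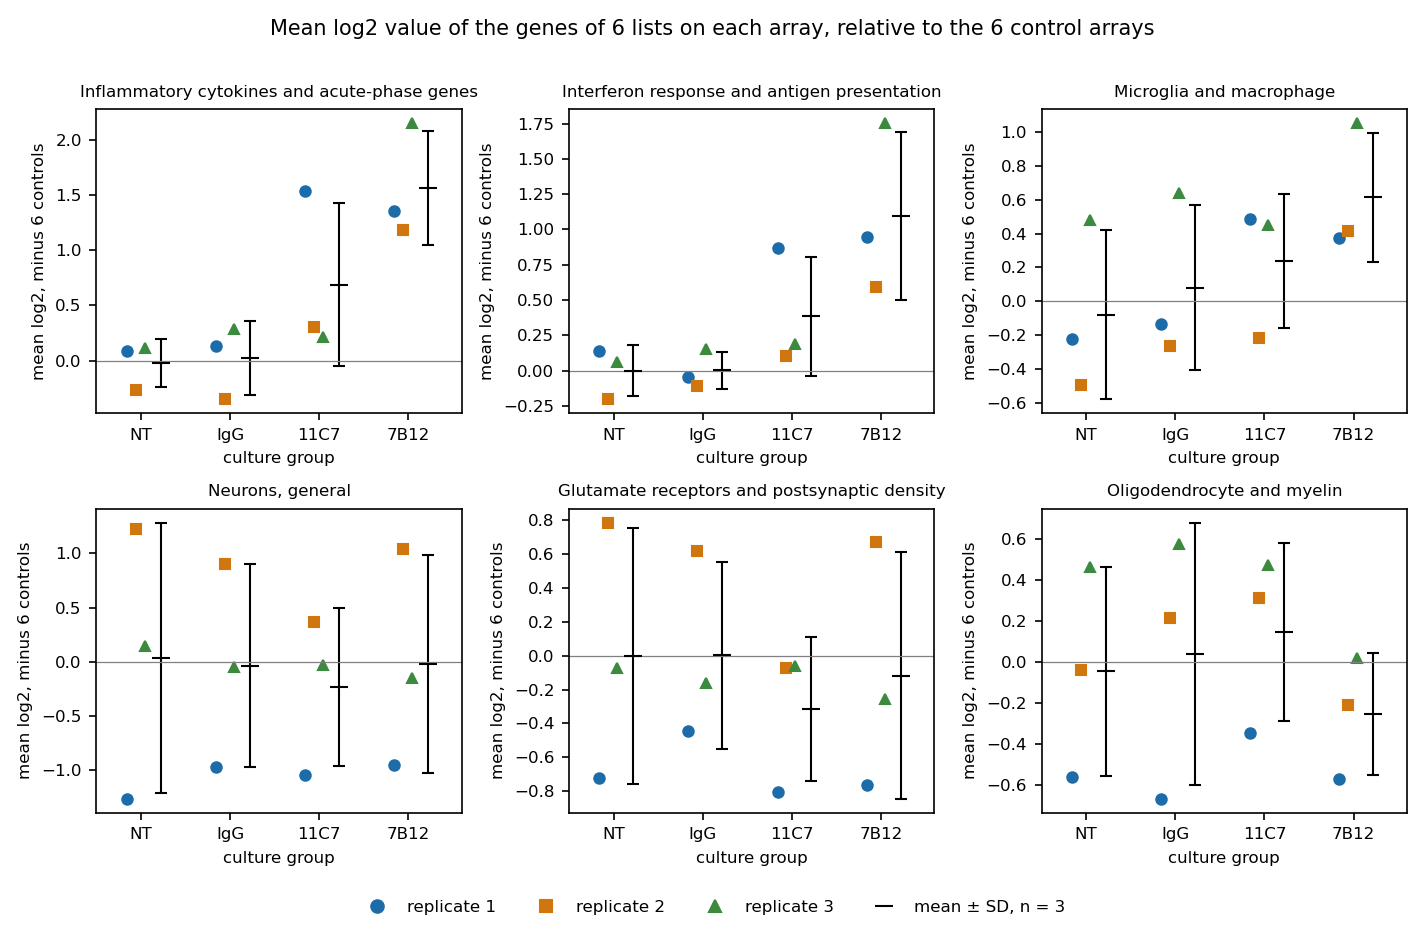
Mean log2 value of the genes of 6 lists on each array, less the mean of the 6 control arrays, for NT, IgG, 11C7 and 7B12; points are arrays, their shape gives the replicate number, and the bar with error shows the group mean and SD (n = 3), with a vertical scale of its own in each panel. The inflammatory list lies between 1.19 and 2.15 in the 3 7B12 arrays and at 1.54 in 11C7 1, with 0.28 the highest control, while general neuron markers follow the replicate number.

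The mean of both antibodies was set against the mean of both controls to ask which genes differ on average over the 2 antibodies. Such an average can rest on 1 antibody or on 1 array of the other. Inflammatory genes rose by a median of 1.00 (2.00-fold, 35 of 37 members above 0) and interferon genes by 0.75 (1.69-fold, 32 of 35 above 0). Saa3 stood 5.11 ± 1.08 (SE) above the controls, Cxcl10 2.11 ± 0.45, Isg15 1.75 ± 0.38 and Oas1a 1.54 ± 0.36. The log2 value of Saa3 was 6.62, 0.02 and 0.61 in 11C7 1, 2 and 3, against -2.17 to 0.06 in the controls. That of Gbp2 was 1.97, 0.60 and -0.33 in these arrays, against -0.33 to 0.20 in the controls. Fc receptor and complement genes rose by 0.38 (15 of 19), microglial markers by 0.23 (23 of 29) and ribosomal protein genes by 0.13 (25 of 27). Blood cell markers stood at a median of 0.67 beside them (7 of 9 members above 0, adjusted p = 0.0600), with means of 1.02, -0.27 and 0.61 in the 11C7 arrays. Fcgr3a stood 1.13 ± 0.33 above the controls, Cybb 1.19 ± 0.33, Lyz2 0.87 ± 0.25 and Rpl22 0.27 ± 0.13. Glutamate receptor genes fell (median change -0.17, 33 of 43 members below 0), with Grin2c at -0.59 ± 0.20 and Grik2 at -0.41 ± 0.16. GABA genes fell by 0.23 (11 of 16), with Gabra2 at -0.61 ± 0.21, astrocyte markers fell by 0.10 (16 of 23), with the angiotensinogen gene Agt at -0.56 ± 0.17 and the clusterin gene Clu in the other direction at 0.65 ± 0.20, and axon guidance genes fell by 0.09 (29 of 47), with Nrp1 at -0.80 ± 0.29 and Epha3 at -0.73 ± 0.30. The inflammatory and interferon means lay above those of the controls of the same number in 6 of 6 antibody arrays. In 11C7 3 the inflammatory mean did so by only 0.018 and, at 0.22, lay below IgG 3 (0.28). The Fc receptor, microglial and blood cell means lay above those of the controls of the same number in 5 of 6. The unfolded protein and heat shock mean did so in 6 of 6 too. Other lists reached 5 of 6 as well, such as ribosomal proteins and handling stress.

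Camera passed these 9 lists with adjusted p = 6.84e-21 for inflammatory genes (adjusted p = 0.300 with an estimated correlation), 8.70e-17 for interferon (0.330), 6.08e-05 for Fc receptor (0.755), 4.19e-05 for microglial (0.774) and 0.00266 for ribosomal genes (0.843). For the lower lists it was 0.00113 for glutamate receptors (adjusted p = 0.843 with an estimated correlation), 0.0155 for astrocytes (0.755), 0.0357 for axon guidance (0.402) and 0.0383 for GABA genes (0.774). Adjusted over the list alone, 14 inflammatory, 11 interferon and 6 microglial genes passed, all higher. The calls of the lower lists ended without single arrays: glutamate receptors without NT 2 (adjusted p = 0.406, median 0.022), IgG 2 (0.313, median 0.019) or 7B12 1 (0.108, median -0.054), and astrocytes without NT 2 (0.0597), IgG 2 (0.0843), 11C7 2 (0.189, median -0.067) or 7B12 3 (0.131, median -0.048). The axon guidance call ended without NT 2 (0.170, median -0.011), IgG 2 (0.110, median -0.039), 11C7 2 (0.0537), 11C7 3 (0.0588) or 7B12 3 (0.240, median -0.041). That of GABA genes ended without NT 2 (0.493, median 0.12), IgG 2 (0.348, median -0.054), 11C7 1 (0.147, median -0.13), 11C7 3 (0.0588), 7B12 1 (0.231, median 0.0067) or 7B12 3 (0.240, median -0.14). The ribosomal call ended without NT 1 (0.0657, median 0.087), IgG 1 (0.0790, median 0.080), 11C7 3 (0.0637) or 7B12 3 (0.330, median 0.061). Under the block no median of the 9 turned sign without 1 array. Calls ended there for glutamate receptors without 11C7 2 (adjusted p = 0.306, median -0.025), for astrocytes without IgG 2 (0.0683), 11C7 2 (0.455) or 7B12 3 (0.222), and for axon guidance without NT 2 (0.0638, median -0.044), IgG 2 (0.0505), 11C7 2 (0.146, median -0.059) or 7B12 3 (0.152, median -0.053). The GABA call ended under the block without NT 2 (0.224, median -0.10), NT 3 (0.120), IgG 1 (0.0932), IgG 2 (0.0560), 11C7 2 (0.388, median -0.0097) or 7B12 3 (0.222, median -0.12). With 11C7 2 placed in the block of number 1, the glutamate receptor median turned to 0.030 (adjusted p = 0.651) and the GABA median to 0.041 (0.596), and the astrocyte (0.113) and axon guidance calls (0.0915) ended. Against IgG alone the calls of axon guidance (adjusted p = 0.122), astrocytes (0.122), GABA (0.180) and ribosomal genes (0.193) ended. Array weights ended those of axon guidance (0.0655), GABA (0.0648) and ribosomal genes (0.158). The probe set of the smallest SD for each gene ended those of axon guidance (0.0865) and GABA genes (0.154), and quantile normalization ended that of GABA genes (0.0771).

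Among the lists that did not pass in this comparison, Nogo-A receptors and signalling had a median of -0.03 (mean 0.02, adjusted p = 0.952), axon growth and regeneration 0.05 (0.579), actin and microtubule regulators 0.03 (0.632), neurotrophins -0.04 (0.579) and presynaptic vesicle genes -0.07 (0.579). The myelin median was -0.01 (adjusted p = 0.295), that of general neuron markers -0.09 (0.286), of interneurons -0.11 (0.145), of unfolded protein genes 0.07 (0.294) and of cell cycle genes 0.13 (0.0668). With the number as a block the last 4 of these passed, at 0.0424, 0.0424, 0.0453 and 0.0172, and none did with the block and an estimated correlation (adjusted p = 0.568 or more). Of single genes, Ptges stood 2.49 ± 0.49 above the controls, Gbp2 1.85 ± 0.37, the folate receptor gene Folr2 1.65 ± 0.34, Serping1 0.99 ± 0.21 and Adam22 1.23 ± 0.20, though Adam22 was at -0.17 against IgG alone. Lower were Mmrn2 (-1.30 ± 0.30), Eif2s3y (-0.81 ± 0.18) and the proline dehydrogenase gene Prodh (-0.55 ± 0.13). By limma 0 of 31042 probe sets passed (smallest adjusted p = 0.675), and 1342 had an unadjusted p under 0.05. Of these, 1340 had at least 1.2-fold, 734 higher and 606 lower (2343 with the replicate number as a block, 1274 higher and 1069 lower).

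**Figure D2:**
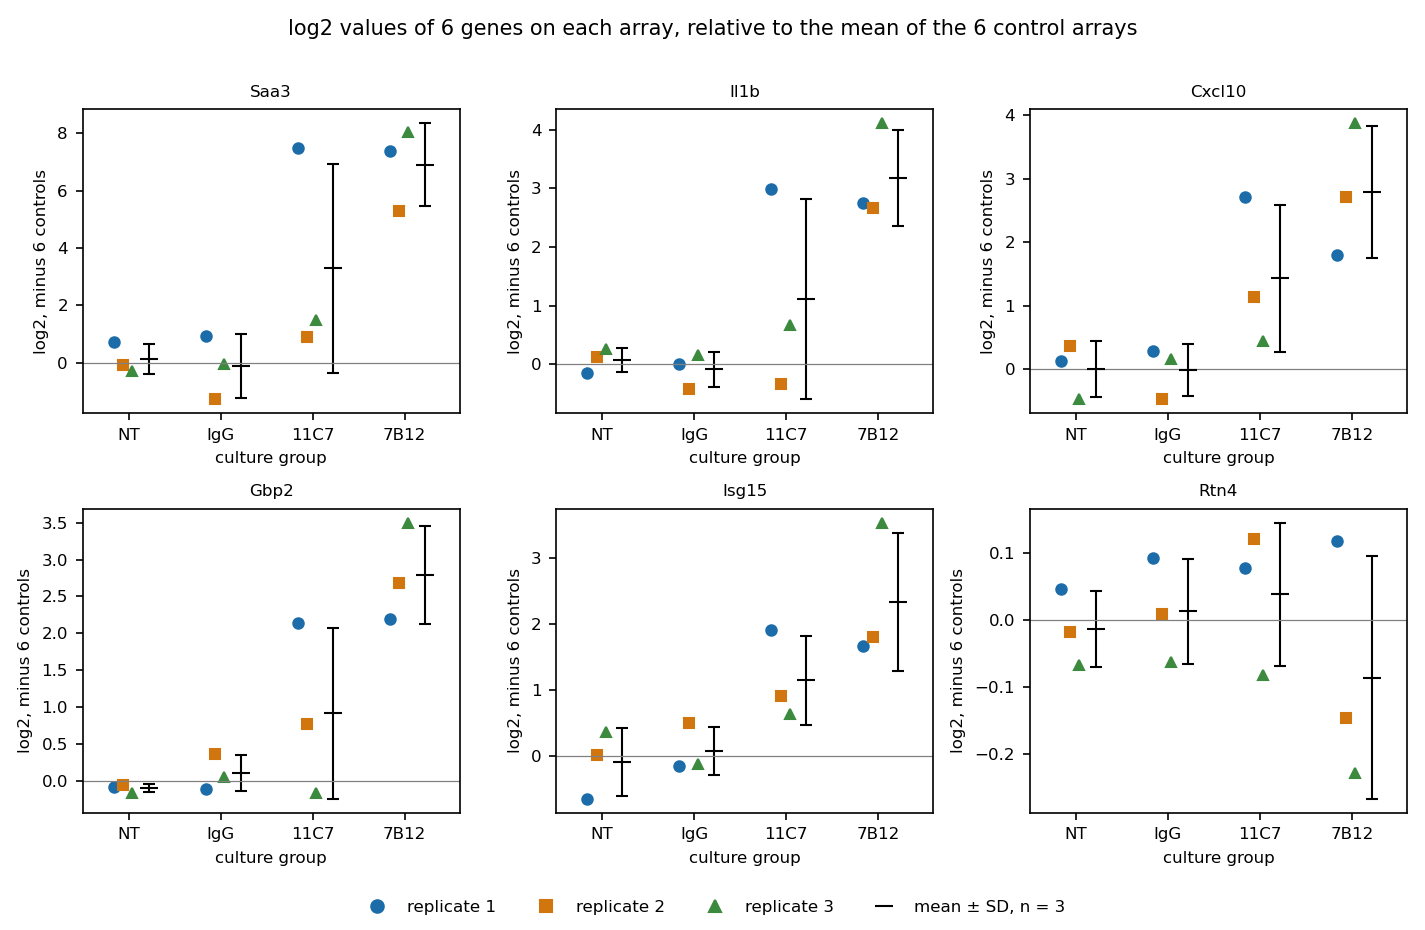
Log2 values of Saa3, Il1b, Cxcl10, Gbp2, Isg15 and Rtn4 on each array, less the mean of the 6 control arrays, for NT, IgG, 11C7 and 7B12; points are arrays, their shape gives the replicate number, and the bar with error shows the group mean and SD (n = 3), with a vertical scale of its own in each panel. Gbp2 in 7B12 averaged 2.79 above the controls, and Rtn4 in both antibodies lay -0.02 from them.

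Rtn4, the gene of the antibodies' target, has 2 probe sets on the array. The mean of the first was 0.06 ± 0.06 (SD, n = 3) in NT, 0.09 ± 0.08 in IgG, 0.12 ± 0.11 in 11C7 and -0.01 ± 0.18 in 7B12. Both antibodies less both controls came to -0.02 (95% confidence interval -0.27 to 0.23), with p = 0.734 by an exact permutation test over 924 splits. The other came to -0.03 (-0.34 to 0.28), with an exact permutation p of 0.790. Because the antibodies act on the protein, this mRNA checks nothing about the labels. The receptor genes had larger errors. Rtn4r, which encodes the Nogo-66 receptor, stood at -0.81 ± 0.65 (SE) and its co-receptor gene Lingo1 at -0.49 ± 0.55, while Rtn4rl2 stood at 0.66 ± 0.85 and the p75 receptor gene Ngfr at 0.45 ± 0.43. Rtn4rl1 stood at -0.19 ± 0.35, the co-receptor gene Tnfrsf19 at -0.09 ± 0.19 and S1pr2, encoding a receptor for another stretch of Nogo-A, at 0.34 ± 0.23. None passed, and in 7B12 alone S1pr2 stood 0.66 ± 0.28 above the controls (adjusted p = 0.938), higher in 3 of 3 arrays.

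IgG was compared with NT to see what a control antibody changes. Fibroblast, meningeal and mural cell markers fell (median change -0.22, 22 of 27 members below 0), with the prostaglandin D synthase gene Ptgds at -1.36 ± 0.59 and the fibulin gene Fbln1 at -1.54 ± 0.71. Blood cell markers rose by a median of 0.52 (7 of 9 members above 0), with Ahsp, which encodes a haemoglobin-stabilising protein, at 3.35 ± 0.66 from a dim probe set, and ribosomal protein genes by 0.12 (24 of 27), with Rpl7 at 0.64 ± 0.33. The inflammatory median was 0.00 (adjusted p = 0.837), the interferon median 0.05 (0.837), the Fc receptor median 0.03 (0.879) and the microglial median 0.10 (0.260). Adam22 stood 2.79 ± 0.29 higher in IgG (adjusted p = 0.0875, 3 of 3 arrays), the transferrin receptor gene Tfr2 1.25 ± 0.26 higher, and Cdca4 (-1.21 ± 0.24) and Ap5z1 (-1.93 ± 0.40) lower. Camera passed the 3 lists with adjusted p = 0.00546 for fibroblasts (adjusted p = 0.973 with an estimated correlation), 0.0306 for blood cells (0.527, and 0.0533 with the number as a block) and 0.0306 for ribosomal proteins (0.985). Adjusted over the list alone, Ahsp passed. The blood cell median was 0.012 with the probe set of the smallest SD for each gene (adjusted p = 0.235), and its adjusted p was 0.496 with only probe sets whose 12-array median was 1. It ended also with the mean-variance trend (adjusted p = 0.0814), with 11C7 2 placed in the block of number 1 (0.0861) and, as the ribosomal call did, with quantile normalization (0.0598 for each). The ribosomal call ended with array weights (0.179). Each call ended without NT 1 (adjusted p = 0.141, 0.0515 and 0.699, with medians of -0.27, 0.80 and -0.0021), IgG 2 (0.180, 0.149 and 0.122, the last with a median of 0.074) or IgG 3 (0.179, 0.179 and 0.791, the last with a median of 0.032), and those of blood cells and ribosomal proteins also without NT 2 (0.158 for each). Under the block the fibroblast call ended without NT 1 (adjusted p = 0.0702), NT 2 (0.106), IgG 2 (0.572) or IgG 3 (0.0864) and the ribosomal call without NT 1 (0.132, median 0.065) or IgG 2 (0.682, median 0.034). By limma 0 of 31042 probe sets passed, and 719 had an unadjusted p under 0.05, all with at least 1.2-fold, 408 higher and 311 lower.

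The antibodies were compared directly, since they bind different stretches of Nogo-A at the same concentration. In 7B12, inflammatory genes were higher than in 11C7 by a median of 0.70 (1.62-fold, 35 of 37 members above 0) and interferon genes by 0.66 (1.58-fold, 33 of 35), with Gbp2 at 1.88 ± 0.52 (SE), Il1b at 2.07 ± 0.73, the chemokine gene Cxcl9 at 1.86 ± 0.73 and the adhesion gene Vcam1 at 1.16 ± 0.50. Fc receptor genes were higher by 0.43 (15 of 19) and microglial markers by 0.35 (20 of 29), with Fcgr3a at 1.05 ± 0.47, Lyz2 at 1.05 ± 0.36 and Cybb at 1.14 ± 0.47. Fibroblast and mural markers were higher by 0.27 (22 of 27), with the actin gene Acta2 at 0.46 ± 0.17 and the collagen gene Col1a1 at 0.82 ± 0.38. Oligodendrocyte and myelin markers were lower in 7B12 (median difference -0.42, 28 of 28 members below 0), among them Car2 at -0.81 ± 0.26, Gpr37 at -0.51 ± 0.22 and Mobp at -0.63 ± 0.29. Precursor markers were lower too (median difference -0.26, 8 of 9 members below 0), with Pdgfra at -0.52 ± 0.22 and Olig2 at -0.36 ± 0.18. By number, 7B12 less 11C7 came to -0.18, 0.89 and 1.93 for the inflammatory mean, 0.080, 0.49 and 1.57 for interferon, -0.086, 0.69 and 0.63 for Fc receptor, -0.11, 0.63 and 0.61 for microglial and -0.12, 0.94 and -0.063 for fibroblast genes. The myelin and precursor means were lower in 7B12 in 3 of 3 numbers.

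Camera passed these 7 lists with adjusted p = 1.73e-09 for interferon (adjusted p = 0.648 with an estimated correlation), 1.93e-09 for inflammatory (0.648), 7.92e-06 for myelin (0.859), 0.00149 for Fc receptor (0.859), 0.00387 for microglial (0.859), 0.0203 for fibroblast (0.859) and 0.0290 for precursor genes (0.648). Adjusted over the list alone, no gene of them passed. The Fc receptor and microglial calls ended without 11C7 2 (0.263 and 0.380, with medians of 0.17 and 0.10) or 7B12 3 (0.150 and 0.311, with medians of 0.099 and 0.12). The fibroblast call ended without 11C7 2 (0.207), 7B12 1 (0.0673) or 7B12 2 (0.174), and the precursor call without 11C7 3 (0.155), 7B12 2 (0.135) or 7B12 3 (0.0852). Leaving out 1 array under the block ended only the fibroblast call, without 11C7 1 (adjusted p = 0.0956), 11C7 2 (0.0557, median 0.17) or 7B12 2 (0.447, median 0.11). That call ended also with the probe set of the smallest SD for each gene (0.0676), and the precursor call with 11C7 2 placed in the block of number 1 (0.0740). The block gave 15 lists, and 0 with an estimated correlation as well. The additions (adjusted p = 0.629 or more with both) were presynaptic (0.0389), glutamate receptor (0.0389), immediate early (0.0254) and ribosomal genes (0.0147) and markers of neurons in general (0.0254), hippocampal principal neurons (0.0199) and interneurons (0.00138), all higher in 7B12, and lower cholesterol genes (0.00685). The neuronal additions differed by number: 7B12 less 11C7 came to 0.67 to 0.96 in number 2 and -0.19 to 0.12 in the others. In numbers 1, 2 and 3 it came to -0.27, 0.060 and 0.25 for ribosomal genes and to -0.10, 0.35 and 0.15 for immediate early genes. Of single genes, Crkl (1.68 ± 0.27), Fap (2.13 ± 0.39) and Cdh8 (2.21 ± 0.45) were higher in 7B12, and Mmrn2 (-2.03 ± 0.42), Irx1 (-2.44 ± 0.53) and Cd200r1l (-1.69 ± 0.42) lower. By limma 0 of 31042 probe sets passed (smallest adjusted p = 0.166), and 1189 had an unadjusted p under 0.05, all with at least 1.2-fold, 808 higher and 381 lower (2178 with the replicate number as a block, 1236 higher and 942 lower).

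Over the 4 groups together, limma's F test passed 0 of 31042 probe sets (smallest adjusted p = 0.0950), with 1099 at an unadjusted p under 0.05. The one-way analysis of variance at p up to 0.05 with a 1.2-fold limit, which the series' design text describes after a filter on detection calls not applied here, gave 928 probe sets, and 0 after Benjamini-Hochberg adjustment. Changes in 11C7 and 7B12 had a correlation across probe sets of 0.349 and a covariance of 0.113; genes are not independent replicates. Both are set against the same control arrays, and unchanged groups simulated with shared controls gave 0.358 (SD 0.329) and 0.128 (SD 0.141) over 100 draws. These draws carried the differences among the numbers without balancing the groups over them, whereas each real group has 1 array per number. The simulation therefore cannot decide whether the agreement, or the overlap given below, exceeds chance. With the controls split, the correlation was 0.0643 and 0.0512 and the covariance 0.0265 and 0.0213. At an unadjusted p up to 0.05 with 1.2-fold, 111 probe sets were higher with both antibodies (9.47 for independent lists, 136 with an SD of 290 in the simulation) and 87 lower (14.6, and 128 with an SD of 246).

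With 4 arrays per number, 1 of each group, 5545 of 31042 probe sets differed among the numbers by limma at adjusted p under 0.05. General neuron markers were higher in number 2 than in number 1 by a median of 2.22 (adjusted p = 3.12e-15 by camera; adjusted p = 0.208 with an estimated correlation), presynaptic genes by 1.70 (3.69e-13; 0.208) and glutamate receptor genes by 1.00 (8.66e-11; 0.217). Endothelial markers were lower there (median difference -0.73, 2.90e-05; 0.208). Number 3 exceeded number 1 in myelin markers by 0.94 (1.13e-12; adjusted p = 0.532 with an estimated correlation) and in microglial markers by 0.52 (2.39e-06; 0.532).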

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

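Chosen only after the result was seen were the tests of inflamed cultures numbered 1, of a swap of labels, of more microglia, of 11C7 2 within numbers, and of a smaller share of neurons. By camera at its preset correlation on 7B12 less 11C7, a test of the difference itself, 7 lists passed. As many passed in 8 of 10 splits of these arrays and in 3 of 4 splits within numbers, the real one included. That count therefore does not set the antibodies apart from other groupings of the arrays. The median log2 differences of the 7 lists were 0.697 for inflammatory, 0.661 for interferon, 0.432 for Fc receptor, 0.350 for microglial and 0.270 for fibroblast genes, and -0.417 for myelin and -0.261 for precursor genes. None of the 7 passed with an estimated correlation. Signals outside the comparisons lay above the control arrays in the spiked-in controls. The poly-A control ratio was 0.937 in 11C7 2, 0.739 in 11C7 3 and 0.792 in 7B12 3, against 0.466 to 0.709 in the 6 control arrays. The hybridisation control ratio was 1.31 in 11C7 3 and 1.38 in 7B12 3, against 0.596 to 1.26 in the controls. Groups of 3 were not tested for single arrays far from the others.

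Inflammatory genes were high in the 3 7B12 arrays (1.36, 1.19 and 2.15) and in 11C7 1 (1.54), and lower in 11C7 2 (0.30, which is 0.61 above the controls numbered 2) and 11C7 3 (0.22, or 0.018 above those numbered 3). Inflamed cultures numbered 1 are argued against, since NT 1 and IgG 1 averaged 0.113 where the highest other control stood at 0.282 (SD of the controls 0.252), and so is a swap of 11C7 1 with a 7B12 array, since the lowest 7B12 array stood at 1.19. More microglia of the kind in the control cultures would raise their markers as much, but the microglial median in 7B12 was 0.391 against 1.53 for inflammatory genes (SD of the microglial changes 0.853). A wrong label on 11C7 1 alone cannot be told apart from a shared response: its differences from 7B12 1 had an SD of 0.534, smaller than those from NT 1 (0.604) and IgG 1 (0.628), which either would give. Open and untested are a response to Nogo-A being bound, a response to antibody bound to tissue, and a contaminant of an antibody preparation such as endotoxin, any of which may be the source.

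Glutamate receptor genes were lower in 11C7 than in the controls, and 11C7 2 also stood apart from NT 2 and IgG 2 in general neuron markers. Leaving out 11C7 2, a test planned before its result, gave adjusted p = 4.78e-05 (median -0.38 against -0.26 with all arrays), but that test was void: it removes number 2 from 11C7 alone, and the controls numbered 2 stood 1.05 above the other controls in this list. With the number as a block and without 11C7 2, the median was 0.00 and adjusted p = 0.605, so within numbers the difference may come from that 1 array. A smaller share of neurons in it as the whole cause would raise every other cell type alike. Its astrocyte markers stood at -0.398 from NT 2 and IgG 2 (0.104 between these). Myelin, microglial and endothelial markers stood higher, at 0.224, 0.164 and 0.084, but within the gap of those controls (0.252, 0.231 and 0.431). This cannot decide, since it rests on 1 array, and astrocyte differences from same-number controls had an SD of 0.188 in 7B12 (n = 3). Whether 11C7 2 was processed with the arrays numbered 1 cannot be told apart from a lower level in its own cultures, and a response to 11C7 itself is open too: its hybridisation ratio (0.682) lay among theirs (0.596 to 0.751), its poly-A ratio (0.937) above theirs (0.633 to 0.709), it correlated with the arrays of its own number (0.254 to 0.303), and the test with that as the block (median 0.17, adjusted p = 0.458) was void, since it sets an array numbered 2 against the lower controls numbered 1.

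Other splits of the same arrays into groups of the same sizes were fitted for every count, 100 drawn where there were more. Probe sets past the adjusted p numbered 0 in the real split of both antibodies, of 11C7, of 7B12 and of the 4 groups, so each of the 100 splits gave as many whatever it held, which decides nothing about chance; the highest others were 866, 5, 67 and 815. At an unadjusted p up to 0.05 with 1.2-fold, 36 of 100 splits gave as many as the 1340 of both antibodies (highest other 6645), 53 of 100 as the 999 of 11C7 (6905) and 40 of 100 as the 1615 of 7B12 (4858). Of lists past camera, 49 of 100 splits gave as many as the 9 of both antibodies (highest other 18), 67 of 100 as the 5 of 11C7 (19) and 53 of 100 as the 8 of 7B12 (19). Among these splits, which ignore the replicate numbers, chance cannot be excluded. The splits with several times the real count point to a structure of the samples, the replicate numbers. Among splits that exchange arrays only within numbers, 3 of 100 gave as many probe sets as both antibodies (highest other 1498), 2 of 27 as 11C7 (1094) and 1 of 27, the real one, as 7B12 (1011), and for lists 12 of 100 (10), 12 of 27 (9) and 3 of 27 (9). Within numbers the share was thus under 0.05 for the probe sets of both antibodies and of 7B12 at the unadjusted p. It was not under 0.05 for those of 11C7 or for the lists. For 7B12, 1 of 27 is the smallest share possible, and the shares were not adjusted over the counts examined, so chance is not excluded.

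For IgG against NT and for 7B12 against 11C7 there are 10 splits, too few for a share under 0.05. The real and highest other values for IgG were 0 and 2 probe sets past the adjusted p (10 of 10 as large), 719 and 2909 at the unadjusted p with 1.2-fold (8 of 10), and 3 and 16 lists (7 of 10). For 7B12 against 11C7 they were 0 and 3 (10 of 10), 1189 and 3596 (5 of 10), and 7 and 17 lists (8 of 10). With the number as a block and without the other antibody, a setting added after the data were seen, 1 of 27 splits within numbers (3.70%), the real one, gave the 68 probe sets of 7B12, with 4 the highest other. That share is under 0.05 but the smallest that 27 splits can give, for a setting chosen among several, so it does not exclude chance (with the block over all 12 arrays 0 probe sets passed). For 11C7 the real value was 0, which each of the 27 of 27 splits had to reach, and the highest other 0.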

How the results depend on the processing

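Chosen after the data were seen were the settings of probe sets with a median of 1, the pseudocount of 0.1, robust eBayes, the block joined to another setting, the block by hybridisation controls and the probe set with the smallest SD. Over the 5 contrasts, 32 list calls had 1027 results on the same side in the same direction, 202 no longer past the threshold and 3 reversed; 246 gene results had 6097, 21 newly past it and 29 reversed. The cause was not tested, except that leaving arrays out leaves fewer samples. An estimated correlation and fry each left 0 lists in all 5 contrasts. Lists past camera changed from 3 to 1 in IgG with quantile normalization, from 5 to 8 in 11C7 with array weights or only probe sets with a median of 1, and to 3 against IgG alone and 11 against NT alone, and from 9 to 5 in both antibodies against IgG alone or with the block without 11C7 2. Pairing by the replicate block gave 14 lists in 11C7 and 15 in 7B12 less 11C7 (12 and 14 with only probe sets with a median of 1, 12 in 11C7 with only the groups of the contrast, 11 in 7B12 less 11C7 without 11C7 2), and left 0 probe sets past the adjusted p; it changed no call other than those given with their comparisons. The block by hybridisation controls, which makes the groups uneven in the numbers, gave 11 lists in 7B12 less 11C7 and reversed the medians of 11C7 to 0.17 for glutamate receptor, 0.16 for GABA and 0.37 for interneuron genes; in both antibodies the medians turned to 0.030 for glutamate receptor and 0.041 for GABA genes. Calls of probe sets went from 0 to 1 in 7B12 with only its groups, to 68 with the block as well, to 1 in both antibodies against NT alone and to 1 in IgG with only probe sets with a median of 1, where Adam22 passed (adjusted p = 0.0335). At unadjusted p with 1.2-fold they were 1340 in both antibodies, 999 in 11C7, 1615 in 7B12, 719 in IgG and 1189 in 7B12 less 11C7. The F test gave 1099 unadjusted; the methods' analysis of variance with 1.2-fold, without the filter on detection calls, gave 928, and 872 on values over the control median, with 0 after adjustment in each.

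Leaving out each array, without the block or with it, gave 5 (without 11C7 2, with the block) to 15 lists in both antibodies, 1 (without 11C7 1 and the block) to 16 (without 11C7 3, with the block) in 11C7, 6 to 14 in 7B12, 0 to 9 in IgG and 6 to 19 (without 11C7 3, with the block) in 7B12 less 11C7. Without the block, probe sets past the adjusted p were 0 to 1 in both antibodies (1 without NT 2), in 11C7 (1 without IgG 2 or 11C7 3), in IgG (1 without NT 1 or IgG 1) and in 7B12 less 11C7 (1 without NT 1 or 11C7 3), 0 to 10 in 7B12 (10 without 11C7 1) and 0 to 2 in the F test (2 without NT 1). Rtn4 in both antibodies ranged from -0.0748 to 0.0119.

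Genes that did not pass in any of these contrasts turned sign as follows, and the cause was not tested. Over the fits that leave out 1 array, Tnfrsf19 in 7B12 ranged from -0.24 to 0.13, Rtn4r in 7B12 from -2.03 to 0.023, Lingo1 in 7B12 from -0.94 to 0.10, and a probe set of Olig2 in 7B12 from -1.44 to 0.11. In the same fits Rtn4rl1 ranged from -0.38 to 0.000413 in both antibodies and from -0.42 to 0.21 in 7B12, Rtn4rl2 from -0.031 to 0.99 in 11C7 and from -0.052 to 1.72 in 7B12, S1pr2 in 11C7 from -0.30 to 0.25, Rtn4 in 11C7 from -0.00264 to 0.0992 and Cd3g in IgG from -0.15 to 1.01. Tnfrsf19 also became 0.059 with array weights and 0.13 against IgG alone in 7B12, and 0.050 against IgG alone in both antibodies. Ngfr against NT alone became -0.40 in both antibodies, -0.43 in 11C7 and -0.37 in 7B12, and Adam22 in both antibodies -0.17 against IgG alone. In 11C7 the block without 11C7 2 turned Rtn4rl1 to 0.040, S1pr2 to -0.050 and Rtn4 to -0.0143, and the block by hybridisation controls S1pr2 to -0.17 and Rtn4 to -0.00606. Not run were the filter on dim probe sets, its stricter form and the planned pseudocount, since ratios carry no level; without the filter the fit is the one reported. Signal over background is unknown here.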

Other observations

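The exact tests within replicate numbers were chosen after the result was seen. In each, the mean of a list was compared over all exchanges of arrays within a number, two-sided. For both antibodies against both controls (216 exchanges, smallest possible p 0.00926) interferon genes differed by 0.74 (exact p = 0.00926), inflammatory genes by 1.13 (exact p = 0.0185), unfolded protein and heat shock genes by 0.12 (exact p = 0.0185), microglial markers by 0.43 (exact p = 0.0370), genes of handling stress and metallothioneins by 0.17 (exact p = 0.0370) and Fc receptor genes by 0.41 (exact p = 0.0463). The other lists past camera in this comparison had an exact p of 0.0648 or more. None passed after adjustment over the 32 lists (0.198 or more). For 7B12 (27 exchanges, smallest possible p 0.0370), inflammatory (1.57), interferon (1.10), Fc receptor (0.62) and microglial genes (0.62) were higher and precursor (-0.22), astrocyte (-0.18) and axon guidance genes (-0.17) lower at that smallest exact p, with an adjusted p of 0.169. Myelin (exact p = 0.0741) and ribosomal genes (exact p = 0.185), which passed camera, did not reach it. For 11C7 the interferon (0.38), unfolded protein (0.13) and handling stress genes (0.15) reached that smallest p, with an adjusted p of 0.395. Of the other lists past camera, glutamate receptor genes, at -0.31, had an exact p of 0.148. Inflammatory genes had an exact p of 0.0741, interneuron markers 0.111 and GABA genes 0.222.

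Genes outside the fixed lists, named after their values were seen, were also among the 68 probe sets of 7B12 with the number as a block and without the 11C7 arrays. Higher in 7B12 were the lectin genes Clec4a (2.10), Clec4a1 (2.22) and Clec4a3 (2.28), the integrin gene Itgax (2.39), the oxidase subunit gene Ncf1 (2.29), the small GTPase gene Rac2 (1.98), the prostaglandin D synthase gene Hpgds (3.01) and the receptor gene Tlr1 (2.42). The superoxide dismutase gene Sod2 (2.24), the ceruloplasmin gene Cp (1.56) and Nfkbiz, a regulator of NF-kappa B targets (1.72), were higher too. Lower beside Igf1 and Ltc4s were Rasgrp3 (-1.65) and Cfc1 (-1.76). The left-out array 11C7 1 stood about where 7B12 1 did in the higher genes named here, with log2 values of 2.09 against 1.81 for Clec4a3 and 2.31 against 2.11 for Itgax. It did not for Hoxa10 (-3.20 against -0.76), a further higher call from a dim probe set. Of the lower genes, 11C7 1 stood near 7B12 1 for Ltc4s (-1.80 against -1.68) but not for Cfc1 (-0.19 against -2.74). In 11C7 2 and 3 Clec4a3 stood at -0.30 and 0.04. The adjusted p of the named genes in that setting lay under the threshold, the largest over the 68 being 0.0469, and over all 12 arrays no probe set passed in 7B12, without the block (smallest adjusted p = 0.438) or with it (0.291).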
